A study of Drosophila melanogaster with 8 samples.

How the data were processed

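The series measured RNA in ovaries of Drosophila melanogaster adults aged 4 to 6 days. There are 8 libraries in 4 groups of 2: flies carrying the piwi1 and piwi2 alleles, a control for them with the germline driver nos-GAL4-VP16, flies in which RnpS1 was knocked down by a double-stranded RNA in follicle cells (driver tj-GAL4) and a short hairpin RNA in the germline (driver nos-GAL4-VP16), and a control for these with both drivers. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was removed in 2 rounds and strand-specific libraries were sequenced.

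For each library the authors deposited a table of raw read counts per gene and a table of raw read counts per transposon family, neither of them normalized and neither pooled over replicates. Per the submitters' processing notes, CASAVA 1.8 and 1.8.2, TopHat2 2.0.9, HTSeq 0.5.3p9 and DESeq were used, with the builds dm3 and BDGP5. The aligner and the reference behind the transposon counts are not given in the sources used here. The gene tables hold 15682 identifiers, of which 15002 have a symbol in a later annotation release (BDGP6) and 680 do not. That release differs from the authors' build, so no coordinates are given; it served for names, for the chromosome of a gene and for intron lengths. The gene tables end in rows that name no gene, which stayed out of library sizes and tests. Reads outside any gene were 1.91% to 10.7% and reads of ambiguous assignment 1.19% to 1.63%, each as a percentage of gene counts plus these 2 kinds of reads. Reads aligned to more than 1 place were 43.2% to 66.0% of the sum of all of these and themselves. The sources used here do not say whether such a read was counted once or once per alignment. These percentages may therefore not be shares of reads. Because reads aligned to several places are left out of the gene counts, values of genes with near-identical copies, such as the Hsp70 genes, the U1 snRNA genes, the Jonah proteases and the cecropins, are uncertain. Reads of a hairpin transgene against RnpS1, and of the white marker gene carried by transgenes, could be counted as the endogenous gene.

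Gene counts summed to 46683566 and 50940588 in the piwi mutant libraries and to 37426999 and 47294459 in their controls. They summed to 75869953 and 86692865 in the RnpS1 knockdown libraries and to 75113449 and 48470348 in theirs. Some count was present for 14299 genes. No files held identical values, and replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom between 57.9 and 328. Spearman correlations between replicates, across genes, lay between 0.980 and 0.989. The labels do not say that the libraries came from separate sets of animals, so p-values measure only the spread between these libraries, technical or biological.

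Differential abundance was tested with edgeR 4.0.16 (R 4.3.3), quasi-likelihood, in 1 fit over all 8 libraries with a term per group and no covariate. Genes were kept by filterByExpr (10434 genes) and families by a total of 10 counts or more (123 families, which were all the families in the tables). Library sizes and TMM factors came from the gene counts alone, and levels in CPM are counts scaled to the library size. The fitted contrasts were 4: mutant against its control, knockdown against its control, the difference between these changes, and the RnpS1 control against the piwi control. Benjamini-Hochberg adjustment was made over genes and, separately, over families, with a threshold of 0.05. The fit had 4 residual degrees of freedom, a prior of 2.98 and a common dispersion of 0.104. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. With 2 libraries against 2, an exact two-sided permutation test of a single value cannot go below 0.333, so no such test was used. A gene at 0 in a whole group is given as a bound computed against 3 counts over the group, and a gene with 1 to 3 counts as a ratio of counts with an exact 95% interval. Intervals and bounds cover counting error only, since reads were not marked by molecule.

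The test was tried on simulated data, in which counts for the 10434 genes were drawn from the real means and library sizes. The recovery given here describes these simulated counts only. Fewer genes and families were changed in them than passed in the real piwi comparison, 1147 and 77. Real calls also depended on single libraries, so the share of real changes that was found is not known. In the simulated piwi comparison 48 of 67 genes changed 2-fold, 61 of 67 changed 4-fold and 60 of 66 changed 8-fold were recovered, with 9 false calls. In the simulated RnpS1 comparison the numbers were 37 of 67, 52 of 67 and 57 of 66, with 12 false calls. Of 10 families changed 2-fold, 8 were recovered in the simulated piwi comparison and 4 in the simulated RnpS1 comparison, and at 4-fold 10 of 10 in each, with 1 and 2 false calls.

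The choice of test, contrasts, alternatives, lists and the rule for named genes was made before the data were examined. Named are piwi and RnpS1, the 8 genes with the largest rise and the 8 with the largest fall among those passing with a group mean of 10 CPM or more, the 8 families with the largest rise and up to 4 with the largest fall, and for each list up to 2 passing members per direction, or the member with the smallest p where none passed. For the other contrasts it was the 4 largest per direction, and for genes changed the same way in both comparisons the 4 per direction whose smaller change was largest. Genes named outside this rule were chosen after their values were seen. The 26 gene lists hold 439 names, of which 377 matched and 350 were tested; they cover the exon junction complex and its ASAP partner, the piRNA pathway (nuclear silencing, primary biogenesis, ping-pong amplification, cluster transcription), decay factors and targets, the spliceosome, heterochromatic genes, eggshell, yolk, early somatic ovary, germline, early germline differentiation, muscle, fat body, haemocyte, gut, testis, oviduct, immune, heat shock, apoptosis, repair, cell cycle and ribosomal protein genes. The 5 family lists are LTR, non-LTR and DNA elements and families known for activity in follicle cells or in the germline. Lists were tested with camera (limma 3.58.1) on log2 CPM, at a preset correlation of 0.01, against the other genes or the other families, with adjustment over the 31 lists of a comparison. Camera with an estimated correlation and fry, which asks whether members move on balance in 1 direction, stand beside it.

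Alternatives were DESeq2 1.42.0, median-ratio factors, library totals alone, TMM factors from the families, no low-count filter, the replicate number as a block, fits of the compared groups alone, adjustment over genes and families together, and leaving out each library. Leaving out genes named as ribosomal RNA, the left-out libraries for the list tests, and settings for the overlap other than DESeq2 and the block were added after seeing the data. Overlaps were tested with Fisher's exact test. Plots were drawn with matplotlib 3.10.9. Splice junctions and small RNAs were not analysed here.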

Results

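The data set asks how ovarian RNA changes when Piwi, the Argonaute protein that silences transposons in the nucleus, is lost, and when RnpS1, a partner of the exon junction complex that marks spliced transcripts, is depleted in both follicle cells and germline. Rather than sharing a control, each condition had its own, and every group held 2 libraries with between 37426999 and 86692865 gene counts. Levels are given in CPM of gene counts as mean ± SD with n = 2, fold changes on the log2 scale with their standard error (SE), and p-values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The leading components of all libraries, which held 37.8% and 31.8% of the variance, were computed on genes.

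Transcripts of each targeted gene were lower in the group in which it was mutated or knocked down. Transcripts of piwi (FBgn0004872) fell in the mutant to 187 ± 5.07 CPM from 332 ± 5.05 CPM in its control, a log2 fold change of −0.83 (SE 0.135, adjusted p = 0.0197). In the RnpS1 knockdown, RnpS1 (FBgn0037707) fell to 6.00 ± 3.29 CPM from 44.1 ± 3.90 CPM (log2 fold change −2.88, SE 0.367, adjusted p = 0.0213), which left 13.6% of the control level. That fall was −3.59 without knockdown replicate 1 and −2.40 without replicate 2. In the same libraries piwi fell to 166 ± 19.8 CPM from 391 ± 56.2 CPM (log2 fold change −1.24, SE 0.136, adjusted p = 0.0162), or 42.4% of the control level. RnpS1 stood at 43.0 ± 5.75 CPM in the piwi mutant and 40.98 ± 4.63 CPM in its control (log2 fold change 0.07, SE 0.341, adjusted p = 0.908). Counts per gene do not separate spliced from unspliced piwi transcripts. With any of the 4 libraries of the piwi comparison left out, the adjusted p of piwi lay above the threshold: 0.0950 and 0.117 without mutant replicate 1 or 2, and 0.0706 and 0.108 without control replicate 1 or 2. In the knockdown, the call of piwi was lost without RnpS1 control replicate 1 (0.0900) and in a fit of the 2 groups alone (0.117), and that of RnpS1 without RnpS1 control replicate 1 (0.0995) or 2 (0.0708), without piwi mutant replicate 1 (0.0536) or 2 (0.0528), and in the fit of the 2 groups alone (0.121).

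**Figure D1:**
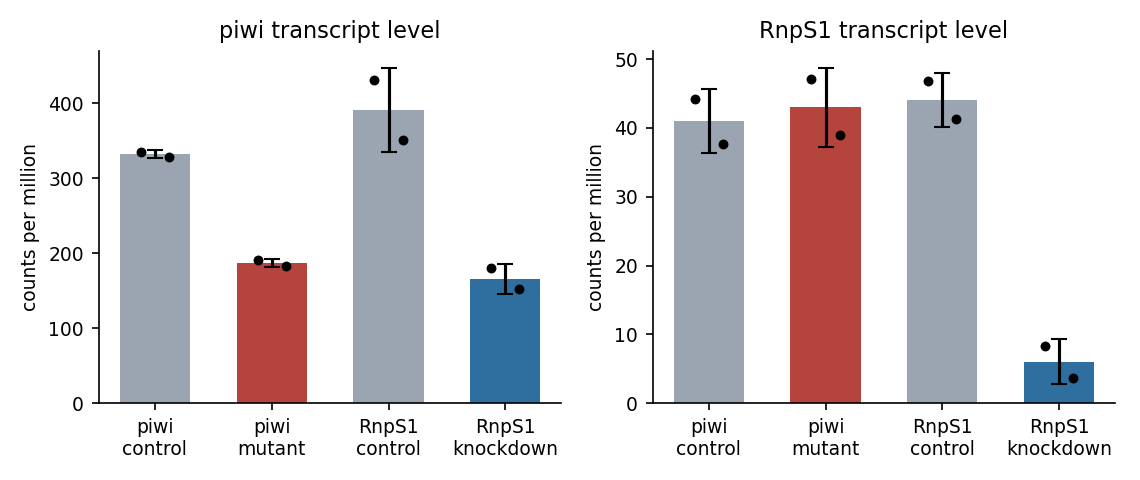
Level of piwi (left) and RnpS1 (right) in CPM of gene counts in the 4 groups. Bars are means, error bars 1 SD and points the 2 libraries; piwi stood at 187 in the mutant against 332 in its control and at 166 in the knockdown against 391, while RnpS1 stood at 6.00 in the knockdown against 44.1.

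Transposon transcripts rose broadly in the piwi mutant. There were 11.4 ± 0.982 transposon counts per 100 gene counts in the mutant and 0.727 ± 0.216 in its control, 15.7 times as many. Of 123 families, 75 rose and 2 fell, 46 did not pass, and 114 had a positive log2 fold change, with a median of 1.22. The largest rises were those of mdg3 (log2 fold change 7.73, SE 0.481; 12266 ± 3718 CPM against 57.7 ± 26.8), copia (6.88, SE 0.530; 29687 ± 1921 CPM against 252 ± 53.2), the telomeric element HeT-A (6.65, SE 0.491), gypsy5 (6.27, SE 0.401), gtwin (6.22, SE 0.359), Burdock (6.07, SE 0.501), 3S18 (5.48, SE 0.421) and diver (5.40, SE 0.430). Their adjusted p-values lay at or below 4.4e-05. The families that fell were the DNA elements NOF (−1.65, SE 0.509, adjusted p = 0.0251) and hopper (−1.45, SE 0.292, adjusted p = 0.00427). The family hopper was also lower in the RnpS1 control than in the piwi control, and by more. Its fall cannot be told apart from a high level in the piwi control alone. Directions of all families are relative to gene counts. With scaling factors taken from the families themselves, 41 were higher and 48 lower, since that scaling sets the bulk of the families to no change and turns their median to −0.29.

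By class, 48 of 59 LTR families rose in the piwi mutant (48 adjusted over the list alone), with a median log2 fold change of 2.60. Among non-LTR families 14 of 35 rose (14 adjusted over the list alone), HeT-A and TAHRE (4.33, SE 0.301) foremost, with a median of 0.86. Among DNA families 12 of 24 rose, including transib1 (3.92, SE 0.416) and Bari1 (3.57, SE 0.376), and 2 fell (12 and 2 adjusted over the list alone). Their median was 0.92. Of the families known for activity in follicle cells 7 of 8 rose (7 adjusted over the list alone, median 3.32), and of those known for activity in the germline 8 of 14 rose (8 adjusted over the list alone, median 2.46). With factors from the families, the medians of the LTR, follicle-cell and germline lists remained positive, at 1.03, 1.79 and 0.93, and those of the non-LTR and DNA lists turned to −0.70 and −0.58. The families higher and lower were then 34 and 15 of the LTR, 3 and 19 of the non-LTR, 3 and 12 of the DNA, 6 and 1 of the follicle-cell and 7 and 6 of the germline list. Against the other families, camera put the LTR list higher (adjusted p = 2.1e-05, adjusted p = 0.652 with an estimated correlation) and the follicle-cell list higher (0.0268, adjusted p = 0.652 with an estimated correlation), and the latter was lost without piwi control replicate 1 (0.0595). It put the DNA list lower (0.0446, adjusted p = 0.725 with an estimated correlation; lost without control replicate 1, 0.127, or 2, 0.0835), opposite in sign to that list's median and to fry, because the comparison is with other families. The non-LTR list, also ranked lower, did not pass (0.0555) except without piwi control replicate 2 (0.0259) or RnpS1 control replicate 1 (0.0493). The germline list did not pass (0.0940). It passed with the replicate number as a block (0.0339) and when any 1 of the libraries other than those of the piwi control was left out, at adjusted p-values from 0.0269 without mutant replicate 1 to 0.0413 without mutant replicate 2. Reads aligned to more than 1 place, which the gene counts leave out, were 65.3% ± 1.00 in the mutant and 47.3% ± 5.81 in its control, possibly counted once per alignment.

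**Figure D2:**
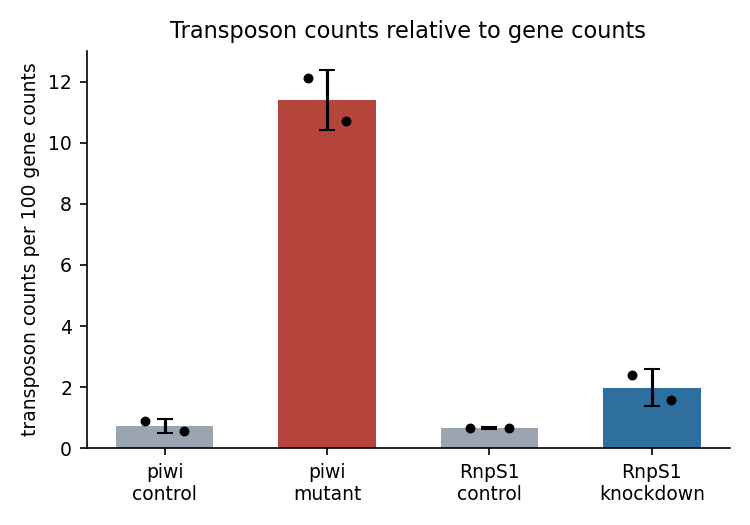
Transposon counts per 100 gene counts in the 4 groups, as deposited. Bars are means, error bars 1 SD and points the 2 libraries; the mutant mean was 11.4 against 0.727, and the knockdown mean 1.99 against 0.660.

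Some eggshell and cell cycle genes fell in the piwi mutant, and the death genes rpr and hid rose. Of 10434 genes tested, 1147 changed, 648 higher and 499 lower, with 590 higher and 101 lower by 2-fold or more; 9287 did not pass. With library totals alone the split was 803 higher and 197 lower, and that scaling moved the median of all genes from 0.01 to 0.17. The count depended on each library of the comparison: it was 44 without mutant replicate 1, 73 without mutant replicate 2, 191 without control replicate 1 and 27 without control replicate 2. Of the 52 genes named for this comparison with a call, 5 kept it with each of the 8 libraries left out, namely CG4021, GstE10, hbt, lncRNA:CR40469 and w, whereas 12 of 13 named families did, NOF being the exception.

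Several of the genes that rose most had almost no counts in the control. CG4021 had 2926 counts in the mutant and 0 in the control, at least 759-fold higher. The metallothionein MtnB had 5303 counts against 3 (ratio 1375, interval 470 to 6669), mthl8 1918 against 1 (1492, 267 to 58954), the odorant-binding protein gene Obp49a 2691 against 2 (1047, 289 to 8646), hbt 2028 against 2 (789, 218 to 6517) and the leucokinin receptor Lkr 1554 against 2 (604, 167 to 4995). The glutathione transferase GstE10 rose by 9.07 (SE 0.686, adjusted p = 0.00395) and lncRNA:CR40469 by 8.80 (SE 0.666, adjusted p = 0.00395). GstE10 was also higher in the RnpS1 control than in the piwi control, by nearly as much. Its rise cannot be told apart from a low level in the piwi control alone. The largest falls were those of sosie (−7.76, SE 1.44, adjusted p = 0.0252), CG14309 (−7.36), the vitelline membrane gene Vm26Ac (−6.46), CG14187 (−6.25), the eye colour gene w (−5.83, SE 0.362, adjusted p = 0.00247), CG31928 (−5.49), the chorion gene Cp7Fa (−5.11) and CG31926 (−4.86). The gene w, a marker of many transgenes, had 299 CPM in the piwi control and 12.4 CPM in the RnpS1 control, whose labels name the same germline driver.

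All 26 tested chorion and vitelline membrane genes, which follicle cells transcribe late in oogenesis, had negative log2 fold changes in the piwi mutant, with a median of −3.54. Of these, 4 fell (8 adjusted over the list alone), Vm26Ac, Cp7Fa, Vm32E (−4.25, SE 1.01) and Fcp3C (−3.59, SE 0.650). Camera gave an adjusted p of 8.2e-08 (adjusted p = 0.652 with an estimated correlation). The 4 yolk protein and yolk uptake genes had a median of −0.87 and none passed, before or after adjustment over the list alone, at an unadjusted p under 0.05, or in DESeq2 (0 each). The receptor gene yl had −0.39 (adjusted p = 0.164). The list median had a camera adjusted p of 0.151, or 0.0251 without either RnpS1 knockdown library. Of 21 germline and oocyte genes 3 fell (6 adjusted over the list alone), namely osk (−0.71, SE 0.114), which directs germ plasm assembly, egl (−0.59; adjusted p = 0.0628 with library totals alone) and bcd (−0.58); 1 fell with library totals alone. The median of the germline list was −0.35 (camera adjusted p = 0.00039, adjusted p = 0.652 with an estimated correlation). Of 11 genes of early germline differentiation, bam, which starts cystoblast differentiation, rose (1.19, SE 0.287; 147 ± 3.33 CPM against 64.6 ± 18.6), and 5 rose when adjusted over the list alone (median 0.54, camera adjusted p = 0.0493, adjusted p = 0.652 with an estimated correlation). That camera call was lost without mutant replicate 1 (0.128) or 2 (0.0524), control replicate 1 (0.127) or 2 (0.0523), or RnpS1 control replicate 2 (0.0546). Of 15 early somatic ovary genes upd2, a JAK/STAT ligand gene (3.72, SE 0.727), and bab2 (2.27, SE 0.504) rose, and 3 when adjusted over the list alone (median 0.93, camera adjusted p = 0.0323, adjusted p = 0.725 with an estimated correlation). It was lost with library totals alone (0.0814) and without mutant replicate 2 (0.0806), control replicate 2 (0.246), or RnpS1 control replicate 1 (0.0596) or 2 (0.0582).

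Of 25 cell cycle genes, 23 had negative values in the piwi mutant and 7 fell (16 adjusted over the list alone, 4 with library totals alone), among them CycE (−0.86, SE 0.119, adjusted p = 0.0145) and the replication licensing gene dup (−0.80, SE 0.138, adjusted p = 0.0214). The median of the cell cycle list was −0.44 (camera adjusted p = 5.2e-06, adjusted p = 0.652 with an estimated correlation). The others were Rbf, stg, CycB3, dap and Cdk2; Rbf and dap are known to restrain the cycle and the rest to drive it. Blm fell (−0.55, SE 0.132; adjusted p = 0.10 with library totals alone) among 17 DNA damage and repair genes, none of which passed when adjusted over the list alone (0, against 4 lower at an unadjusted p under 0.05 and 2 lower in DESeq2). Their median was −0.21 and camera gave an adjusted p of 0.0208 (adjusted p = 0.725 with an estimated correlation), lost without mutant replicate 2 (0.0752) or control replicate 2 (0.112). Of 12 apoptosis and p53 response genes 3 rose (4 adjusted over the list alone), the death genes rpr (4.91, SE 0.667; 5.37 ± 0.203 CPM against 0.177 ± 0.0302) and hid (2.11, SE 0.343) and the p53 target Corp (1.21, SE 0.161). The list's median was 0.34 and its camera adjusted p 0.0555, or 0.0495 with library totals alone. None of 40 cytosolic ribosomal protein genes passed, also over the list alone (0, against 15 lower at an unadjusted p under 0.05, 9 lower in DESeq2), although 36 had negative values. The list median was −0.24 (camera adjusted p = 0.00029, adjusted p = 0.652 with an estimated correlation). RpS6 had −0.45 (adjusted p = 0.0592). Of 14 heat shock genes the chaperone gene DnaJ-1 fell (−0.76, SE 0.135; 1 adjusted over the list alone, median −0.44, camera adjusted p = 0.268), and the list passed without piwi control replicate 2 (1.1e-05).

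Many markers of tissues that surround or adjoin the ovary had positive values in the piwi mutant. All 14 muscle genes had positive values, with a median of 2.53, although none passed, also over the list alone (0, against 7 higher at an unadjusted p under 0.05, 4 in DESeq2). Mlc2 had 3.39 (SE 1.2, adjusted p = 0.106), and camera gave 0.0135 (adjusted p = 0.725 with an estimated correlation), lost without mutant replicate 2 (0.0632) or control replicate 2 (0.112). Of 7 fat body and haemolymph genes 3 rose (4 adjusted over the list alone), the transferrin gene Tsf1 (4.76, SE 1.06; 141 ± 112 CPM against 5.17 ± 2.87) and the lipoprotein genes Apoltp (2.80) and apolpp (2.64). Their median was 2.80 (camera adjusted p = 0.0240, adjusted p = 0.652 with an estimated correlation). That call was lost with library totals alone (0.0618) and without mutant replicate 2 (0.0632) or control replicate 2 (0.0978). Of 10 haemocyte and basement membrane genes NimC1 (7.22, SE 1.54) and Hml (4.75, SE 1.06) rose, and 4 when adjusted over the list alone (median 1.61, camera adjusted p = 0.167). All 13 gut protease and amylase genes had positive values, with a median of 3.12; none passed, also over the list alone (0, against 0 at an unadjusted p under 0.05, 1 higher in DESeq2), and betaTry had 293 counts in the mutant against 2 (ratio 114, interval 31.3 to 945; adjusted p = 0.197), at 0.0404 and 5.42 CPM in the 2 mutant libraries. The per-library medians of log2 CPM over the muscle list were 6.65 and 7.73 in the mutant and 4.96 and 3.54 in the control, those over the eggshell list 1.78 and 5.15 against 7.75 and 7.06, and those over the gut list −3.40 and 1.5 against −3.07 and −3.67, so that the gut values were higher in mutant replicate 2 alone. Of 8 testis genes can (45 counts against 1; ratio 35.0, interval 5.97 to 1413) and mia (1.84, SE 0.432) rose (2 adjusted over the list alone, median 0.47, camera adjusted p = 0.284). Of 3 oviduct and spermatheca genes Send1 rose from 0 to 157 counts, at least 40.7-fold, and 1 rose and 1 fell when adjusted over the list alone; the list's median was −0.04 and its mean 2.72, and the median turned to 0.12 with library totals alone. Of 17 immune genes PGRP-SB1 rose (3.05, SE 0.764, median 1.28, camera adjusted p = 0.268), and none when adjusted over the list alone (0, against 3 higher at an unadjusted p under 0.05, 4 in DESeq2).

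Components of the silencing and RNA surveillance machinery changed by less than 2-fold in the piwi mutant. All 9 nuclear silencing genes had negative values, with a median of −0.29, and 3 fell (3 adjusted over the list alone): piwi, mael (−0.46, SE 0.0780) and the histone methyltransferase gene egg (−0.41, SE 0.0959; camera adjusted p = 0.00593, adjusted p = 0.652 with an estimated correlation). Among 10 ping-pong genes tapas fell (−0.63, SE 0.103; 1 adjusted over the list alone, median −0.18, camera adjusted p = 0.144). None of 13 primary biogenesis genes (0, against 1 lower at an unadjusted p under 0.05, 1 in DESeq2) or of 10 cluster transcription genes (0, against 1 higher and 3 lower, and 1 higher and 2 lower in DESeq2) passed, also over the list alone; SoYb had −0.39 (adjusted p = 0.0654) and Boot −0.33 (adjusted p = 0.0792). Their medians, −0.08 and −0.11 (camera adjusted p = 0.284 and 0.332), turned to 0.08 and 0.05 with library totals alone. Of 7 nonsense-mediated decay factors 3 fell (3 adjusted over the list alone), Smg6 (−0.79, SE 0.152), Smg5 (−0.71, SE 0.15) and Upf1 (−0.57, SE 0.116). With library totals alone none of them passed (0.0520 for Smg6 and 0.0665 for Smg5), nor did btz (0.0906), Acn (0.0934) or mael (0.0561), and 1 nuclear silencing gene fell. The list median was −0.29 (camera adjusted p = 0.0173, adjusted p = 0.652 with an estimated correlation). Among 7 exon junction complex and ASAP genes mago rose (0.48, SE 0.0765), and btz (−0.63, SE 0.156) and Acn (−0.47, SE 0.103) fell, with the same numbers adjusted over the list alone (1 and 2); the list's median was 0.07, its mean −0.05, and camera placed it lower (adjusted p = 0.705). None of 5 decay-sensitive transcripts passed, also over the list alone (0, against 1 higher at an unadjusted p under 0.05 and in DESeq2, median 0.18, camera adjusted p = 0.781). Arc1 had 1.12 (adjusted p = 0.144). None of 16 spliceosome and SR protein genes passed, also over the list alone (0, against 1 lower at an unadjusted p under 0.05, 0 in DESeq2). Prp8 had −0.39 (adjusted p = 0.155), and the median of −0.01 (camera adjusted p = 0.637) turned to 0.15 with library totals alone. Of 16 heterochromatic genes Snap25 rose (3.84, SE 0.731; 1 adjusted over the list alone, median 0.06, camera adjusted p = 0.569).

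In the RnpS1 knockdown, transposons rose in fewer families and by less than in the piwi mutant. There were 1.99 ± 0.591 transposon counts per 100 gene counts in the knockdown and 0.660 ± 0.0221 in its control, 3.01 times as many. Of 123 families 22 rose, and in edgeR 0 fell, with 33 at an unadjusted p under 0.05 in either direction and 0 lower in DESeq2; 85 had a positive value and the median log2 fold change was 0.19. The largest rises were those of Tirant (5.15, SE 1.13; 15.4 and 178 CPM in the 2 knockdown libraries against 2.73 ± 0.466), 412 (3.87, SE 0.390), GATE (3.58, SE 0.635), P-element (3.40, SE 0.301), copia (3.15, SE 0.445; 7140 ± 4620 CPM against 802 ± 47.7), diver (2.74, SE 0.381), mdg1 (2.59, SE 0.427) and Burdock (2.43, SE 0.424). Their adjusted p-values lay between 0.00060 (P-element) and 0.0235 (Tirant). P-element ends are also part of common transgene vectors. Of 12 named families with a call, 412, copia, diver, mdg1 and P-element kept it with each library left out, and the count of 22 was 10 without RnpS1 control replicate 1. With factors from the families 21 were higher and 5 lower, with a median of −0.02, and with adjustment over genes and families together 12 were higher.

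By class, 17 of 59 LTR families rose in the knockdown (18 adjusted over the list alone, median 0.41), with a camera adjusted p of 0.0133 (adjusted p = 0.920 with an estimated correlation), lost without RnpS1 control replicate 2 (0.0509). Of 35 non-LTR families HeT-A rose (1.49, SE 0.392, median 0.16, camera adjusted p = 0.201), and none when adjusted over the list alone (0, against 5 higher and 1 lower at an unadjusted p under 0.05, 5 higher in DESeq2). Of 24 DNA families 4 rose (4 adjusted over the list alone), P-element, Bari1 (1.46, SE 0.345), transib3 and pogo. The median of the DNA list was 0.06 (camera adjusted p = 0.225). Of the follicle-cell families 2 of 8 rose (2 adjusted over the list alone), Idefix (1.37, SE 0.363) and gtwin (1.10, SE 0.291; list median 0.22, camera adjusted p = 0.929). Of the germline families 5 of 14 rose (6 adjusted over the list alone), including diver and Burdock, and all 14 had positive values (median 0.46, camera adjusted p = 0.147). Camera ranked the non-LTR and DNA lists below other families although their medians were positive, and with factors from the families the medians of the non-LTR, DNA and follicle-cell lists turned to −0.07, −0.14 and −0.03. The families higher and lower were then 17 and 1 of the LTR, 1 and 2 of the non-LTR and 3 and 2 of the DNA list.

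**Figure D3:**
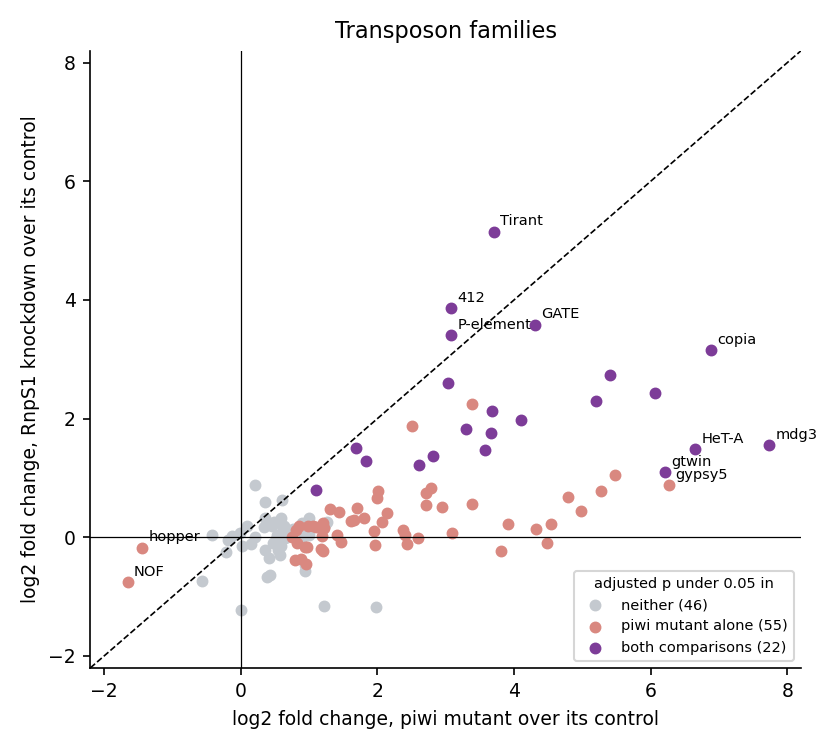
Log2 fold change of the 123 transposon families in the piwi mutant (horizontal) and the RnpS1 knockdown (vertical), each over its own control and relative to gene counts, coloured by the comparisons in which edgeR's adjusted p was under 0.05. The 22 families that rose in the knockdown also rose in the mutant, and all but 412, P-element and Tirant lie below the dashed line of equal change; with scaling from the families themselves 48 families were lower in the mutant and 5 in the knockdown.

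With all libraries, fewer genes changed in the RnpS1 knockdown than in the piwi mutant at the same threshold, among them falls of the germline regulators Sxl and mei-P26. The order of these counts turned without piwi control replicate 2. Of 10434 genes 161 changed, 90 higher and 71 lower, with 82 higher and 31 lower by 2-fold or more. With library totals alone the split was 121 and 45, a scaling that moved the median of all genes from 0.01 to 0.12. CG11911, a serine protease gene, had 3436 counts against 1 (ratio 2413, interval 433 to 95346), at 4.44 and 34.5 CPM in the 2 knockdown libraries. The heat shock gene Hsp70Bb rose by 8.40 (SE 1.09, adjusted p = 0.0216; 137 ± 15.0 CPM against 0.373 ± 0.315). Further rises were those of CG43088 (7.58, SE 0.923), CG7953 (6.04, SE 1.03), the dynein gene Dhc98D (5.98, SE 0.404, adjusted p = 0.00466), CG17650 (5.14), CG18131 (5.09) and a gene without a symbol, FBgn0052595 (8.02). Next to RnpS1, the largest falls were those of the glutathione transferase GstE1 (−2.69, SE 0.302, adjusted p = 0.0162), the transcription factor Cph (−2.46, SE 0.320), CG6163 (−1.70), CG1774 (−1.53), CG15312 (−1.51), unc-13 (−1.48) and the pseudouridine synthase Pus10 (−1.45). Of the 30 named genes with a call in edgeR 0 kept it with each library left out. The count of 161 became 0 without RnpS1 control replicate 1 and 21 without replicate 2, 34 without knockdown replicate 1, 28 without either piwi mutant library, and 91 and 87 without piwi control replicate 1 or 2. A fit of the 2 groups alone called 5 genes, whereas with all libraries 1890 had an unadjusted p under 0.05 in edgeR and DESeq2 called 975.

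Among 11 genes of early germline differentiation, Sxl (−1.10, SE 0.184, adjusted p = 0.0456) and mei-P26 (−0.97, SE 0.108, adjusted p = 0.0162) fell in the knockdown, and 3 rose and 2 fell when adjusted over the list alone (median 0.32, camera adjusted p = 0.762). Of 25 cell cycle genes 3 fell (3 adjusted over the list alone), the ribonucleotide reductase gene RnrL (−0.85, SE 0.147), Cdk4 (−0.69, SE 0.112) and Cdk2 (−0.66, SE 0.108), and 24 had negative values (median −0.35, camera adjusted p = 2.1e-06, adjusted p = 0.891 with an estimated correlation). With library totals alone none of these 3 passed (0.0733 for RnrL and 0.0631 for Cdk4), nor did Sxl (0.0593). The kinase gene tefu fell (−0.94, SE 0.115; 1 adjusted over the list alone) among 17 repair genes (median −0.19, camera adjusted p = 0.0133, adjusted p = 0.920 with an estimated correlation), a list call lost without knockdown replicate 2 (0.125) or RnpS1 control replicate 1 (0.196). Of 12 apoptosis and p53 response genes Xrp1 rose (1.14, SE 0.154; 1 adjusted over the list alone). The list median was 0.27 (camera adjusted p = 0.0452, adjusted p = 0.891 with an estimated correlation). That list call was lost without knockdown replicate 1 (0.339), RnpS1 control replicate 2 (0.276), piwi mutant replicate 1 (0.0733) or 2 (0.0761), or piwi control replicate 1 (0.0544). Of 14 heat shock genes Hsp70Bb rose and Hsp26 fell (−0.80, SE 0.122), or 2 and 1 adjusted over the list alone; the median was 0.99, or 0.49 with the gene at 0 counts set to its bound, and the camera adjusted p was 0.451 (0.0141 and 0.0138 without piwi control replicate 1 or 2).

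Eggshell genes had negative values in the knockdown too, 26 of 26 with a median of −0.98, but none passed, also over the list alone (0, against 0 at an unadjusted p under 0.05 and in DESeq2). The gene ndl had −1.34 (adjusted p = 0.347). The list medians of log2 CPM overlapped, with 5.71 and 7.93 in the knockdown libraries and 6.97 and 8.57 in the control libraries. Camera gave 0.0133 (adjusted p = 0.920 with an estimated correlation), lost without knockdown replicate 1 (0.615) or RnpS1 control replicate 2 (0.218). None of the 4 yolk genes passed, also over the list alone (0, against 0 at an unadjusted p under 0.05 and in DESeq2; median −0.97). The gene yl had −0.39 (adjusted p = 0.292). Their camera adjusted p was 0.0452 (adjusted p = 0.891 with an estimated correlation), and the call was lost without piwi mutant replicate 1 (0.0522) or 2 (0.0538), piwi control replicate 1 (0.0544), knockdown replicate 1 (0.279), or RnpS1 control replicate 1 (0.0620) or 2 (0.15). Of 21 germline and oocyte genes 20 had negative values and none passed, also over the list alone (0, against 3 lower at an unadjusted p under 0.05, 3 in DESeq2). The gene stau had −0.50 (adjusted p = 0.108), and the median was −0.17 (camera adjusted p = 0.00698, adjusted p = 0.891 with an estimated correlation), lost without RnpS1 control replicate 1 (0.0707). None of 16 heterochromatic genes passed, while 5 fell when adjusted over the list alone (0 over all genes; 1 higher and 6 lower at an unadjusted p under 0.05, 6 lower in DESeq2). Nipped-A had −0.65 (adjusted p = 0.0622). Their median was −0.50 (camera adjusted p = 0.00657, adjusted p = 0.891 with an estimated correlation), lost without knockdown replicate 2 (0.125). None of 10 ping-pong genes passed, also over the list alone (0, against 3 lower at an unadjusted p under 0.05, 2 in DESeq2). The list median was −0.24 (camera adjusted p = 0.0140, adjusted p = 0.891 with an estimated correlation), lost without RnpS1 control replicate 1 (0.0620). The gene tapas had −0.41 (adjusted p = 0.109).

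In the nuclear silencing list 1 of 9 genes fell in the knockdown, piwi, and 3 rose and 1 fell when adjusted over the list alone (median −0.01, camera adjusted p = 0.890 in the upward direction). RnpS1 fell among the 7 exon junction complex and ASAP genes (1 adjusted over the list alone, median −0.08, camera adjusted p = 0.264). No gene passed in the lists of primary biogenesis (0, against 3 lower at an unadjusted p under 0.05, 3 in DESeq2, 1 lower adjusted over the list alone; shu −0.62, adjusted p = 0.0696), cluster transcription (0, against 2 higher and 2 lower, 1 and 1 in DESeq2, 1 higher adjusted over the list alone; Boot 0.45, adjusted p = 0.0869), decay factors (0, against 0 and 0 in DESeq2; Upf3 −0.20, adjusted p = 0.459), decay-sensitive transcripts (0, against 0 and 0; tra −0.50, adjusted p = 0.466) or the spliceosome (0, against 2 lower, 0 in DESeq2; x16 −0.38, adjusted p = 0.213). Their medians were −0.08, −0.03, −0.15, −0.09 and −0.13, with camera adjusted p-values of 0.135, 0.711, 0.181, 0.827 and 0.0777. Without knockdown replicate 1 the primary biogenesis list passed (0.0433). With library totals alone the medians of the exon junction complex (0.04), nuclear silencing (0.10), primary biogenesis (0.04), cluster transcription (0.08) and decay-sensitive (0.03) lists turned positive.

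Tissue markers did not pass in the knockdown: muscle (0 of 14, against 0 at an unadjusted p under 0.05 and in DESeq2, median 0.13, camera adjusted p = 0.782; Tm1 −0.25, adjusted p = 0.333), fat body (0 of 7, against 0 and 0; −0.33, 0.890; Apoltp −0.94, adjusted p = 0.438), haemocyte (0 of 10, against 0 and 0; −0.22, 0.827; srp −0.29, adjusted p = 0.792), gut (0 of 13, against 1 higher, 1 in DESeq2; 0.55, 0.225; Jon44E 6.21, adjusted p = 0.125) and testis (0 of 8, against 2 higher, 0 in DESeq2; 0.68, 0.438; aly 103 counts against 2, adjusted p = 0.133). The mean of the gut list was −0.25, opposite in sign to its median, and without RnpS1 control replicate 1 that list passed as higher (0.00017). Its medians of log2 CPM were 2.05 and 2.75 in the knockdown libraries and 3.88 and −4.17 in the control libraries. The muscle list passed as lower without RnpS1 control replicate 1 (0.0404) and as higher without replicate 2 (0.00431), with medians of log2 CPM of 4.11 and 5.83 in the knockdown libraries and 2.70 and 5.93 in the control libraries. For early somatic ovary genes (0 of 15, against 1 higher and 1 lower at an unadjusted p under 0.05, in DESeq2 and adjusted over the list alone) the median was 0.71 (camera adjusted p = 0.387), with zfh1 at −0.92 (adjusted p = 0.0774). Immune genes (0 of 17, against 1 higher, 0 in DESeq2) had a median of 1.11 (camera adjusted p = 0.520), with Dso1 at 2.58 (adjusted p = 0.204), and passed without knockdown replicate 2 (0.0373). Oviduct genes (0 of 3, against 0 and 0; Send1 2 counts in the control and 0 in the knockdown) had a median of −0.47 (camera adjusted p = 0.762). Ribosomal protein genes (0 of 40, against 0 and 0) had a median of 0.04 (camera adjusted p = 0.827), with RpL38 at 0.49 (adjusted p = 0.312). In these lists other than early somatic ovary 0 genes passed when adjusted over the list alone. At an estimated correlation camera called 0 of 31 lists in either comparison (1 each at an unadjusted p under 0.05), and fry called 12 in the mutant and 0 in the knockdown.

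**Figure D4:**
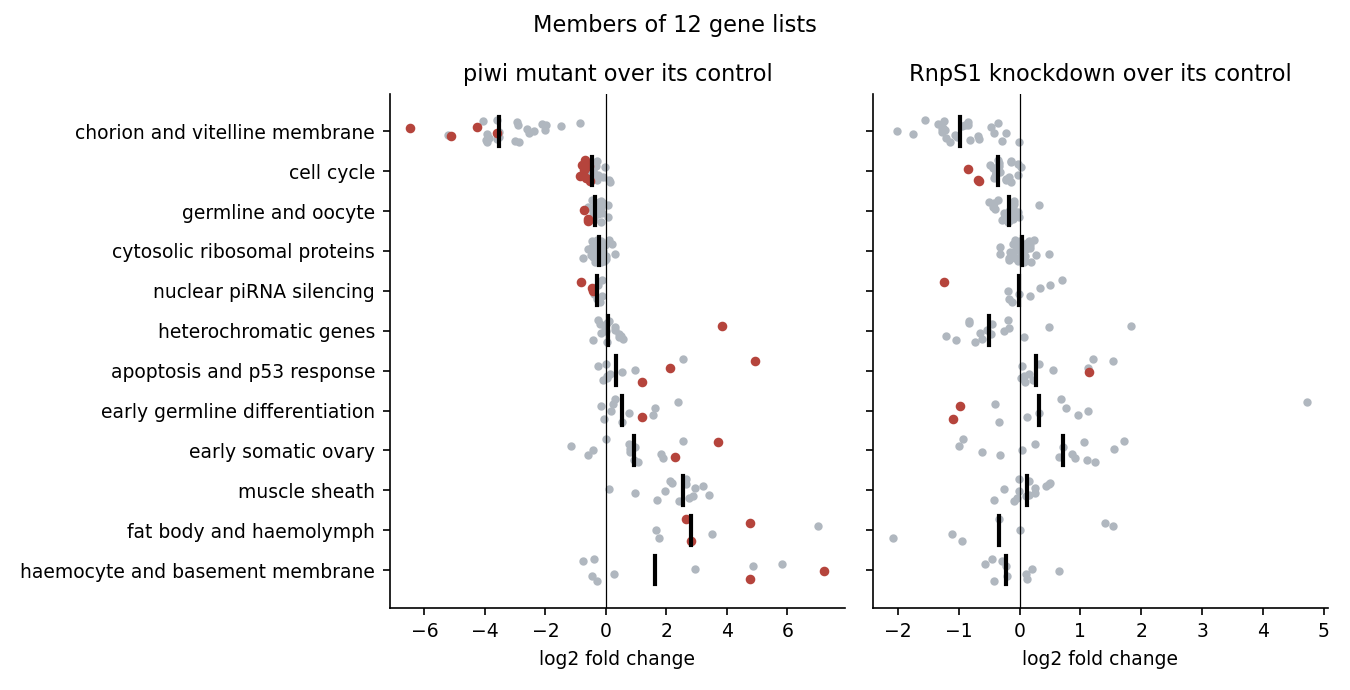
Log2 fold changes of the members of 12 gene lists in the piwi mutant (left) and the RnpS1 knockdown (right), each over its own control. Points are genes, red where edgeR's adjusted p was under 0.05, and black bars list medians; eggshell genes had a median of −3.54 in the mutant and −0.98 in the knockdown, muscle genes 2.53 and 0.13.

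Calls of the 2 comparisons, which share no library, overlapped more than independent lists would. Both come from 1 fit that shares its estimate of the spread of each gene, so the calls are not independent. Genes are not independent of one another either, so the p-values describe the overlap only. Families that rose in the knockdown were 22, and each of these also rose in the mutant, where 13.4 would be shared by independent lists (Fisher's exact test, adjusted p = 7.1e-06). Among genes 25 rose in both (5.59 for independent lists, odds ratio 6.00, adjusted p = 4.3e-10) and 14 fell in both (3.40, odds ratio 5.0, adjusted p = 7.1e-06). The steroid synthesis gene spok rose in both, from 3 to 427 counts in the mutant (ratio 111, interval 37.6 to 539) and by 6.86 (SE 1.07) in the knockdown. CG33958 rose from 0 counts in each control, by at least 11.9-fold in the mutant and 37.7-fold in the knockdown. CG15534 rose at least 8.30-fold in the mutant and from 2 to 404 counts in the knockdown (ratio 142, interval 39.0 to 1176), and CG18853 by 6.06 (SE 0.804) in the mutant and at least 36.1-fold in the knockdown. GstE1 fell in both (−3.10 and −2.69), as did CG1774 (−1.47 and −1.53), PlexB, a receptor gene of axon guidance (−1.05 and −0.99), and FBgn0022772, which has no symbol (−1.01 and −1.02). The 39 genes shared in direction became 0 without RnpS1 control replicate 1, 5 without its replicate 2, 3 or 4 without piwi mutant replicate 1 or 2, 13 or 4 without piwi control replicate 1 or 2, and 10 without knockdown replicate 1; the 22 families became 10 without RnpS1 control replicate 1.

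Tested directly, the change differed between the comparisons for 47 families and 67 genes. In 46 of the 47 families the log2 fold change was lower in the knockdown, most so for mdg3 (difference −6.18, SE 0.550), gypsy5 (−5.40), HeT-A (−5.16) and gtwin (−5.12), and in hopper it was higher (1.27, SE 0.408, adjusted p = 0.0477). Among genes 29 had a higher and 38 a lower value in the knockdown. The families became 70 without piwi control replicate 1. Without RnpS1 control replicate 1 or 2 the genes became 9 and 30, without knockdown replicate 1 or 2 they became 40 and 27, without mutant replicate 1 or 2 12 and 22, and without piwi control replicate 1 or 2 25 and 16.

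The 2 control groups, which differ in the tj-GAL4 driver by their labels, also differed from each other. Between them 371 genes passed, 163 higher and 208 lower in the RnpS1 control, and 36 families, 5 higher and 31 lower. GstE10 was higher in the RnpS1 control (8.79, SE 0.683; 23.2 ± 4.81 CPM against 0.0536 ± 0.0444), as were CG43163 (6.97), snRNA:U1:82Eb (6.31, SE 0.546), which has near-identical copies, and the ribosomal DNA element R2-element (3.47, SE 0.881), Osvaldo (1.73), copia (1.67) and gypsy3 (1.34). Hsp70Ab was lower, with 1 count against 1544 (ratio 0.00044, interval 1.1e-05 to 0.0024), as were hopper (−2.89, SE 0.308), Stalker3T (−2.80), 1731 (−2.62) and diver (−2.19). The other large differences were in genes without a symbol. FBgn0085827 was higher in the RnpS1 control (7.31, SE 0.949). FBgn0085823 was at least 18280-fold lower, and FBgn0085797 (−12.45) and FBgn0085815 (−10.52) were lower. Of the 1147 genes changed in the mutant 115 also differed between the controls, and of the 161 changed in the knockdown 33 (20.5%). Among families these were 23 of 77 in the mutant (22.5 for independent lists) and 11 of 22 in the knockdown (6.44). Each of these comparisons shares a control group with that of the controls, which alone makes calls overlap. The counts became 44 genes without piwi control replicate 1, 51 without its replicate 2, 66 and 62 without RnpS1 control replicate 1 or 2, and 108 and 107 without piwi mutant replicate 1 or 2; the families were 6 without RnpS1 control replicate 1, 56 without piwi control replicate 2, and 16, 21 and 22 without piwi control replicate 1 and mutant replicates 1 and 2.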

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

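Of the tests in this part, those of chromosome 2, of a larger share of other tissues, of tissue carried over per list, of a weak knockdown library and of the loss of piwi transcripts were chosen after the result they measure was seen. The tests of alleles silent in the piwi control, of tissue carried over in 1 library over all lists and of lower starting levels were written down before. Results are given here where the change differed between the comparisons by a direct test, or where a measure outside the main counts lay above its controls.

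Changes of transposon families differed between the comparisons for 47 families, and 46 of these had the lower change in the knockdown. Lower starting levels in the piwi control would give such a pattern without lower levels in the knockdown itself, but in a direct comparison of these groups 101 of all 123 families were lower in the knockdown than in the mutant and 3 higher. The 46 families, whose choice already rests on these levels, included 45 of them (97.8%). Between the controls 31 families were lower in the RnpS1 control and 5 higher, the opposite of lower levels in the piwi control. Both of these comparisons cross the piwi and RnpS1 experiments, so differences in handling or background can be part of them. Reads outside any gene were 4.45% to 10.7% in the piwi mutant and control libraries and 1.91% to 3.29% in the knockdown and control libraries. The levels argue against lower starting levels only as far as the experiments can be compared. A weak rise in 1 knockdown library is argued against by the number of families called as rising less, which stayed at 76.1% of its value or more when either knockdown library was left out. A smaller loss of piwi transcripts was also considered. The change of piwi counts was lower in the knockdown than in the mutant by −0.41 on the log2 scale. This cannot decide the question, since counts in the mutant come from the piwi1 and piwi2 alleles. Counts per gene also do not show how much of the transcript was spliced or translated. What stays open is a smaller loss of piwi in the knockdown, and the difference between a mutant and a knockdown, which the design names and these data did not test.

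Large gene changes in the piwi mutant were set against the genetic background of the flies. Of the genes called with a change of 4-fold or more, 226 of 529 lay on chromosome 2, which holds piwi (42.7% against 37.7% of other genes). The odds ratio was 1.23 (interval 1.03 to 1.48, Fisher's exact p = 0.0213, adjusted p = 0.108), which lies between the bounds set for and against variants on that chromosome, so these cannot be told apart from other sources. Over all called genes the odds ratio was 1.24 (466 of 1096, adjusted p = 0.0130), with 1.32 for the rises (adjusted p = 0.0130) and 1.11 for the falls (adjusted p = 0.543). Called genes were fewer on the X chromosome (odds ratio 0.76, adjusted p = 0.0280), which raises the share of the other chromosomes. In the knockdown, where the labels name no piwi allele, the odds ratio for chromosome 2 was 2.01 at 4-fold or more (33 of 60, adjusted p = 0.0512) and 1.15 over all called genes (62 of 150, adjusted p = 0.569). Between the controls it was 1.48 at 4-fold or more (65 of 137, adjusted p = 0.119). Of the genes higher by 4-fold or more, 7.66% (38 of 496) were also higher in the RnpS1 control than in the piwi control. This argues against alleles silent in the piwi control alone as the main source. The share counts only genes that passed between the controls, where 163 of 10434 genes were higher, so it can miss such alleles. The loss of Piwi itself stays open, as the group differs in both.

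Markers of muscle, fat body, haemocytes and gut had positive medians in the piwi mutant of 2.53, 2.80, 1.61 and 3.12. Over all members the median log2 ratio to the control was 1.62 in the lower of the 2 mutant libraries and 3.49 in the other, which met the bound set against tissue carried over in 1 library but hid a difference between lists. For muscle and fat body such carry-over is argued against by the ratios in the lower library, 2.20 (bootstrap SE 0.211) and 2.41 (0.771). These SE cover the spread among members of a list and not that between libraries. Medians of log2 CPM over the fat body list were 4.59 and 5.54 in the mutant and 1.67 and −2.78 in the control. The control libraries thus lay far apart, although both were below both mutant libraries. For haemocytes it cannot be told apart from other sources, as the spread among members is wide (1.53, bootstrap SE 1.85). For gut it stays open, since the ratio was −0.21 (bootstrap SE 0.399) in replicate 1 and 4.07 in replicate 2. A larger share of all these tissues, alike for each, cannot be told apart from other sources, as the medians lay 1.52 apart with a standard error of 2.0, too wide to decide. The eggshell medians of log2 CPM, 1.78 and 5.15 in the mutant libraries, moved in the other direction from the control's 7.75 and 7.06. Changes within the ovary were not separated from changes in its share.

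The change differed between the comparisons for 67 genes. The value, as knockdown change minus mutant change on the log2 scale, was 10.23 for w, which had 5.26 CPM in the mutant, 299 in its control, 263 in the knockdown and 12.4 in its control. It was 9.95 for Hsp70Bb, 9.26 for Dhc98D and 6.65 for narya. It was −15.09 for CG4021, −9.73 for hbt, −9.12 for CG42326 and −9.06 for GstE10. GstE10 was higher in the RnpS1 control than in the piwi control by nearly as much. Fitted values of genes with 0 to 3 counts in a group depend on the prior count. Calls of Dhc98D and w were kept with each library left out, and the other 6 were not. Among families the value was 1.27 for hopper, −6.18 for mdg3, −5.40 for gypsy5, −5.16 for HeT-A and −5.12 for gtwin. The last 4 kept their call with each library left out and hopper did not. Like GstE10, hopper also differed between the controls, being lower in the RnpS1 control.

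Of 3 kinds of reads outside the main counts, 2 were more frequent in both piwi mutant libraries than in both of their controls. Reads aligned to more than 1 place, possibly counted once per alignment, made up 65.3%, against 47.3% in the control, and reads of ambiguous assignment 1.58%, against 1.41%. Reads outside any gene were not (8.67% and 7.80% against 10.7% and 4.45%). In the RnpS1 control, reads aligned to more than 1 place were 44.9% in replicate 1 and 65.3% in replicate 2. Replicates of 1 group can thus differ by as much. With 2 libraries against 2 the smallest two-sided permutation p is 0.333.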

How the results depend on the processing

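The settings added after seeing the data were the list tests without single libraries, the overlap under settings other than DESeq2 and the block, and the removal of genes named as ribosomal RNA. No named gene or family with a call turned its direction. With families scaled by their own factors, 41 were higher and 48 lower in the mutant. A library left alone in its group is assumed to vary like the others. DESeq2 gave more genes: 2431 in the mutant, 975 in the knockdown, 762 for the difference, 1406 between the controls and 366 shared, with 57 families between the controls. Without a count filter 112 genes differed in change. With the replicate block the genes were 624, 64, 44, 207 and 14 in the same order. The labels do not say whether equal numbers pair libraries, and deviations of equal numbers correlated at −0.18 and 0.21 across genes and −0.17 and 0.26 across families in the mutant and knockdown comparisons. Pairing stays open. In fits of the compared groups alone, with fewer samples, the knockdown had 5 genes, the controls 123 genes and 21 families, and the overlap 1 gene. Adjusting over genes and families together gave 12 families in the knockdown, 23 for the difference, 14 between controls and 12 shared, as more values were adjusted at once. Camera with an estimated correlation called 0 and 0 lists.

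With each library left out, genes ranged from 27 to 1085 in the mutant, 0 to 119 in the knockdown, 9 to 40 for the difference, 44 to 340 between controls and 0 to 50 shared. Families ranged from 59 to 98 in the mutant, 10 to 26 in the knockdown, 33 to 70 for the difference, 6 to 56 between controls and 10 to 26 shared. Of 164 named results, 47 kept their direction and side of the threshold in each of the settings run for them, up to 17 each. The block lost 33 calls, fits of the compared groups alone 37, library totals 10, and leaving out 1 library between 29 and 82. For the other changes the cause was not tested. Gene counts between 37426999 and 86692865 per library limit genes with few counts.

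Directions turned, without a call, for RnpS1 in the mutant (log2 fold change from −0.057 to 0.21 with each library left out) and srp in the knockdown (−0.78 to 0.35). Camera's direction turned in some setting for 15 of 62 list tests, and with a call in 1 of them, muscle in the knockdown. With each library left out, adjusted p-values of these lists in the mutant ranged from 0.0947 to 0.702 for gut, 1.1e-05 to 0.369 for heat shock, 0.246 to 0.857 for heterochromatic and 0.498 to 0.962 for oviduct genes. In the knockdown they ranged from 0.276 to 0.993 for decay-sensitive transcripts, 0.0373 to 0.745 for immune, 0.667 to 0.964 for ribosomal protein, 0.345 to 0.924 for fat body, 0.00017 to 0.590 for gut, 0.0620 to 0.782 for haemocyte, 0.00431 to 0.830 for muscle, 0.667 to 0.998 for nuclear silencing and 0.0962 to 0.848 for oviduct genes, and 0.626 to 0.936 for follicle-cell families. With library totals alone the direction turned for oviduct (0.979) and spliceosome genes (0.860) in the mutant and muscle (0.930) in the knockdown, and with the block for follicle-cell families in the knockdown (0.942).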

Other observations

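The tests of chromosome 4 and of intron length were written down before their results were seen, although an excess of called genes on chromosome 4 prompted the first. The genes changed in opposite directions and those of chromosome 4 were chosen after their values were seen.

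Of 50 genes called in both comparisons, 11 changed in opposite directions. The eye colour gene w fell in the mutant (−5.83) and rose in the knockdown (4.41), and so did Dhc98D (−3.27 and 5.98), CG17470 (−4.91 and 3.89), Cep164 (−1.37 and 4.02), swaPsi (−2.21 and 2.02), Rtca (−1.41 and 1.51), CG12159 (−1.23 and 1.5), tun (−1.04 and 1.10) and CG1265 (−0.81 and 1.61). The photolyase gene phr6-4 rose in the mutant (2.87) and fell in the knockdown (−1.13), as did Naglu (1.15 and −1.36). Across all 10434 genes, which are not independent replicates, fold changes of the comparisons correlated with Pearson's r = 0.397 and Spearman's rho = 0.448, and across the 123 families with 0.608 and 0.631. The permutation p was 0.0001 in each of these 4 relations, before and after adjustment, the smallest that the permutations can give. The sign was shared by 67.3% of genes and 70.7% of families.

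On chromosome 4, a small and largely heterochromatic chromosome, 15 of 83 tested genes rose in the piwi mutant and 6 fell. Cadps (4.33), fd102C (3.61), Kif3C (2.93), fuss (2.56), mGluR (2.13), Rnf11 (1.8) and Cals (0.82) rose, as did the fat body gene apolpp (2.64), while CR43361 (−3.77), mav (−1.13), PlexB (−1.05), Asator (−0.74), Hcf (−0.52) and gw (−0.46) fell. These made up 1.92% of called genes against 0.699% of the others (odds ratio 2.77, Fisher's exact test, adjusted p = 0.00841 over 96 tests). The odds ratio was 3.40 for the rises (adjusted p = 0.00841) and 1.55 for the falls (adjusted p = 0.544). In the knockdown 5 of the 83 fell, 7.25% of the genes that fell against 0.788% of the others (odds ratio 9.82, adjusted p = 0.00841). For knockdown calls in either direction the odds ratio was 4.30 (adjusted p = 0.0525). Of the 60 knockdown calls at 4-fold or more, 0 lay on chromosome 4. Between the controls the odds ratio was 2.18 over all called genes (interval 0.77 to 5.01, adjusted p = 0.197). At 4-fold or more it was 3.71 between the controls (interval 0.97 to 10.1, adjusted p = 0.119) and 3.37 in the mutant (adjusted p = 0.00953). Neither value between the controls passed, but each interval holds the mutant's value at the same threshold, 2.77 and 3.37. The excess in the mutant therefore cannot be told apart from a difference in genetic background. The excess of falls in the knockdown was not separated from such a difference either.

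A hypothesis was that genes of chromosome 4 rose as a group in the piwi mutant. Their median log2 fold change lay 0.18 above that of other genes (permutation p = 0.019), and between 0.16 and 0.29 with each library left out. The called genes that prompted the hypothesis are part of this median, so it is no separate test and the hypothesis stays open. In the knockdown their median lay below that of other genes, by −0.18 (permutation p = 0.00069, adjusted p = 0.00138), and between −0.24 and −0.11 with each library left out. The called falls are part of this median, and the permutation treats genes as independent, so it is no separate test either. A further hypothesis was that genes with a long intron fell more than others in the knockdown. The 872 genes with the longest introns, of 8719, differed by −0.046 in their median (permutation p = 0.00066), short of the difference set beforehand. Its sign turned without knockdown replicate 1 (0.08) or RnpS1 control replicate 2 (0.04), and it was −0.18 and −0.11 without the others, so the hypothesis was not borne out.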
